A study of Homo sapiens with 5 samples.

How the data were processed

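Nuclei of human gastrocnemius muscle from PAD (3 libraries) and PAD-CKD (2 libraries) were measured by droplet-based single-nucleus RNA sequencing. The authors name Cell Ranger 7.0.0 and the GRCh38 genome, with no role or order for them, and state no filter, background correction or normalization. The deposited values are the natural log of 1 plus 10000 times the UMIs of a gene over the total UMIs of the nucleus, worked out from the values, since the labels do not give the unit. The back-transformed values of every nucleus sum to 10000 and are whole multiples of one step, so UMIs were recovered, and 100% of the recovered values were whole within 0.01. The files give gene symbols without identifiers for each gene, and entries listed with the value 0 are present.

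Nuclei with at least 500 UMIs and at most 5% mitochondrial UMIs were kept. The deposited nuclei already held between 400 and 3996 detected genes and at most 5% mitochondrial UMIs. Scrublet in scanpy 1.11.5 was given an expected doublet rate of 0.06. Its automatic threshold called between 0.0544% and 0.328% of a library, so the nuclei with the highest scores were removed up to that rate instead, 577 to 970 per library. Clustering used 2000 variable genes, 30 principal components, 20 nearest neighbours and the Leiden method (leidenalg 0.10.2, resolution 1), over all libraries without integration and with a fixed random seed of 0. XIST, its neighbours and Y-linked genes, 35 in all, were left out of every table and test. Clusters were named from 20 marker lists written before the data were examined, as were the comparisons, the tests planned for counts, the gene lists and the rule for named genes. A cluster was called myonuclear above 30000 CPM summed over myonuclear markers. A non-muscle name needed a marker score of 3 and a fibre state a score of 1.2 with a margin of 0.5 over the next state (log2), with at least 3 detected markers and a marker among the 50 leading genes. These naming thresholds were chosen after the clusters were seen. The 30 clusters gave 12 classes, counting 1 cluster without a name.

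For each class with at least 20 nuclei in every library, the CPM of each gene was averaged over the nuclei of a library. Values were scaled between libraries by the trimmed mean of M-values (trims 0.3 and 0.05) and taken as log2 of CPM plus 5. Genes with a mean of at least 10 CPM and at least 10 recovered UMIs in at least 2 libraries were tested. The groups were compared by limma 3.58.1 with a trended, robust prior (statmod 1.5.0, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the genes tested in a class and a threshold of 0.05. The comparison of the changes in type I and type II myonuclei used the library as a term. The design planned edgeR for counts, and edgeR and DESeq2 were not run, a choice to match the tests to the deposited log values, although the recovered UMIs would have allowed a test of counts. Mural, mast, T and NK cells had under 20 nuclei in at least 1 library, so their genes were not tested, and other myonuclei were tested only as part of all myonuclei. Fold changes are PAD-CKD over PAD. Unless given from UMI counts, they come from the fit on log2 of CPM plus 5, so they differ from ratios of the CPM printed beside them.

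Of 34 gene lists fixed before, those with at least 5 tested genes in a class were tested with limma camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a class. Camera with an estimated correlation and the limma test fry were run beside it. Class shares were compared by exact two-sided permutation over the 10 splits of the 5 libraries, and intervals of shares are Clopper-Pearson at 95%. Intervals and floors (3 UMIs over a group) cover counting error only.

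The named genes are, per class, the 12 of largest change in each direction among genes past the threshold with a symbol, at least 20 CPM and no overlap between the groups, of which 1 in all myonuclei is left out of the text and the plot. In myonuclei up to 4 members of each list that passed camera were added by smallest p. Where fewer than 5 genes passed, the 3 of smallest p in each direction were taken. The myosin heavy chains and 7 further genes were always given for all myonuclei. For the other classes, members of such lists past the threshold, and the member of smallest p, were added after their values were seen. Gene positions and overlaps between strands come from the GENCODE annotation, release 29, on GRCh38.

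The libraries held 46696899 to 63943194 recovered UMIs. The test was checked on simulated data with 200 changed genes, a squared coefficient of variation of 0.04 and the depth of each class. It recovered 64.2% of 2-fold and 100% of 4-fold changes in all myonuclei, 61.2% and 100% in type I myonuclei, 5.97% and 73.1% in type II myonuclei, and 1.56% and 20.6% in endothelial cells, and 14 of 190 calls in all myonuclei were false. The alternatives set before were median-ratio scaling, no filter on low values, the replicate number as a block, doublets kept, at least 1000 UMIs per nucleus, clustering with genes centred within libraries, genes at least 10 times as abundant in myonuclei left out, the 2 other list tests, and each library left out in turn. Those added after the data were seen were pseudocounts of 1 and 20 CPM, no scaling, sums of recovered UMIs, limma-voom on these sums, entries at 0 counted as 1 UMI, genes opposite a gene at least 10 times as abundant left out, nuclei thinned to 1000 UMIs, means of the log values, and, for class shares, each myonuclear cluster named by its highest fibre state alone, or a fibre state kept only with a marker among the 10 leading genes.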

Results

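Single-nucleus RNA sequencing was carried out on calf muscle (gastrocnemius) of people with peripheral artery disease (PAD, narrowing of the leg arteries), alone or together with chronic kidney disease (PAD-CKD). The series holds 3 PAD libraries and 2 PAD-CKD libraries, prepared with a droplet-based method that reads the 3' end of transcripts. Its description counts 20 PAD patients and 12 PAD-CKD patients. Which patients stand behind which library is not given, so the limma and permutation p-values below measure only the spread between libraries. Camera at the preset correlation and Fisher's exact test compare genes with other genes, which are not independent replicates. Their p-values do not measure that spread. The files hold 14386, 10654 and 11027 nuclei for PAD replicates 1, 2 and 3, and 9611 and 16195 nuclei for PAD-CKD replicates 1 and 2. The total of unique molecular identifiers (UMIs, which mark single captured transcripts) ranged from 46696899 to 63943194 per library. The median nucleus held between 2948 and 5518 UMIs and between 1447 and 2120 detected genes, depending on the library.

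The comparison asks how muscle affected by both diseases differs from muscle affected by PAD alone, first in the kinds of nuclei present. Myonuclei, the nuclei of the muscle fibres, made up 89.0% ± 3.94 (SD, n = 3) of the nuclei in PAD and 72.8% ± 7.93 (SD, n = 2) in PAD-CKD. Fibro-adipogenic progenitors, the connective tissue cells of muscle, made up 4.45% ± 0.797 in PAD and 8.33% ± 0.526 in PAD-CKD. Macrophages and monocytes made up 1.33% ± 0.941 and 4.19% ± 1.59, endothelial cells 0.614% ± 0.440 and 3.25% ± 1.68, and mast cells 0.0592% ± 0.0206 and 0.252% ± 0.00328. Mural cells of vessel walls made up 0.0386% to 0.359% in the PAD libraries and 0.520% and 2.64% in the PAD-CKD libraries. For these 6 shares all PAD-CKD libraries lay on the same side of all PAD libraries, and each gave p = 0.1 in an exact two-sided permutation test. That is the smallest p that the 10 splits of 5 libraries allow, and after Benjamini-Hochberg adjustment over the 12 classes the exact p of the last 5 was 0.24, so none of these differences passed a threshold of 0.05. The clustering matters here too, since with genes centred within libraries the difference for all myonuclei was -10.8 percentage points in place of -16.1, the libraries of the groups overlapped (exact permutation p = 0.3), and that for endothelial cells was 4.09 in place of 2.63.

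The shares of fibre nuclei varied widely between libraries of a group. Type I (slow) myonuclei, named by markers such as MYH7 and TNNT1, made up 39.8% ± 13.6 of the nuclei in PAD and 9.80% ± 7.11 in PAD-CKD (exact permutation p = 0.2, Benjamini-Hochberg adjusted p = 0.3), with no overlap between the libraries of the groups. Type II (fast) myonuclei, with MYH1 and MYH2, made up 25.3% ± 22.6 and 26.1% ± 16.5 (exact permutation p = 1). Myonuclei with markers of regenerating or denervated fibres, such as MYH3, RUNX1 and NCAM1, made up 11.0% ± 16.6 and 19.6% ± 0.917 (exact permutation p = 0.4), with 30.1%, 2.43% and 0.396% in PAD replicates 1, 2 and 3, and other myonuclei 12.9% ± 21.1 and 17.3% ± 0.496 (exact permutation p = 1). PAD replicate 1 held 0.407% type II myonuclei (95% Clopper-Pearson interval 0.307 to 0.529, which covers counting error only), against 30.7% and 44.6% in the other PAD libraries. This value rests on the naming, because a cluster of 4937 other myonuclei, 97.7% of them from PAD replicate 1, scored highest for type II, at 0.94 and so below the 1.2 needed for a name. Clustering with genes centred within libraries gave 304 type II myonuclei in PAD replicate 1 in place of 55. The regenerating or denervated-like share rests on it as well, because clusters of 2702 and 1494 other myonuclei, 99.2% and 85.4% from PAD-CKD, scored highest for that state at 1.89 and 1.51 but lacked a further condition for the name. With each myonuclear cluster named by its highest fibre state, that share was 31.6%, 2.66% and 0.569% in PAD replicates 1, 2 and 3 and 34.3% and 37.2% in PAD-CKD, so the groups no longer overlapped (exact permutation p = 0.2). In the other direction, a cluster of 2792 nuclei in the class, 98.1% of them from PAD-CKD, scored 1.29 with no marker among its 10 leading genes, and with such a marker required the share was 10.8% in PAD and 8.68% in PAD-CKD (exact permutation p = 1), so the direction of this difference depends on the naming. The type II share with the highest fibre state was 37.3% in PAD and 26.4% in PAD-CKD (exact permutation p = 0.5). Satellite cells, the stem cells of muscle, made up 2.85% ± 0.705 and 4.48% ± 0.898 (exact permutation p = 0.2), without overlap between the groups, T and NK cells 0.961% ± 1.55 and 1.81% ± 1.80 (exact permutation p = 0.5), and nuclei without a name 0.583% ± 0.639 and 3.27% ± 3.12 (exact permutation p = 0.2). In 5 of the 6 type I clusters, all 6 type II clusters, all 4 regenerating or denervated-like clusters and 3 of the 4 other myonuclear clusters, over 50% of the nuclei came from 1 library. The difference in the share of type II myonuclei was -11.6 percentage points without PAD replicate 1 and -10.8 without PAD-CKD replicate 1, that of other myonuclei -1.73 without PAD replicate 2 and -1.67 without PAD replicate 3, and that of T and NK cells -0.429 without PAD-CKD replicate 2.

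**Figure D1:**
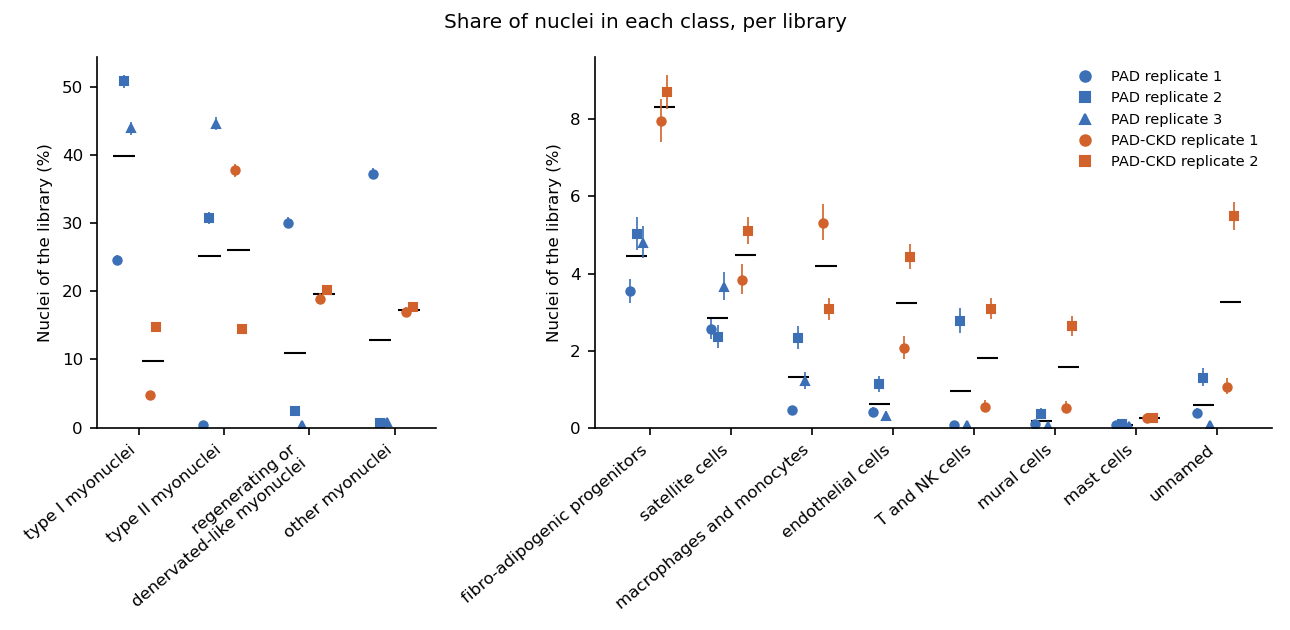
Share of nuclei in each class, in percent of the nuclei of a library, with 1 point per library, 95% Clopper-Pearson intervals as bars and the group mean as a black line. Fibro-adipogenic progenitors lie at 3.54% to 5.02% in PAD and at 7.96% and 8.70% in PAD-CKD, while the shares of fibre nuclei overlap between the groups for type II, regenerating or denervated-like and other myonuclei.

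Across all myonuclei, 221 of 8885 tested genes differed between the groups, 132 of them higher and 89 lower in PAD-CKD (limma on log2 values, Benjamini-Hochberg adjusted p below 0.05). This balance depends on the filter, since without one 223 were higher and 34 lower, and 94 of these 257 genes were among the 221. It also depends on the method, since 1 gene passed by limma-voom on recovered UMI sums and 81 with means of the log values. On the log2 scale with 5 counts per 1000000 (CPM) added, the largest increase among the named genes was in PRUNE2 (chromosome 9, 76611376 to 76906087, minus strand), at 586 CPM ± 118 (SD, n = 2) in PAD-CKD and 33.3 ± 9.27 (SD, n = 3) in PAD, a log2 fold change of 3.94 ± 0.26 (SE; limma, Benjamini-Hochberg adjusted p = 0.0166). The added 5 CPM shrinks the change of genes low in PAD, such as IL21R, so this order depends on it. ANXA1 (chromosome 9, 73151757 to 73170393, plus strand), which encodes the phospholipid-binding annexin A1, stood at 124 CPM ± 21.5 and 4.02 ± 4.52. Of its UMIs in all nuclei, 7741 of 22272 lay in myonuclei in PAD-CKD and 550 of 2839 in PAD, so carry-over from other nuclei is not excluded. IL21R (chromosome 16, 27402162 to 27452042, plus strand), the receptor of interleukin 21, stood at 70.5 CPM ± 1.22 and 0.515 ± 0.286 (limma, Benjamini-Hochberg adjusted p = 0.0057). DKK2 and BMPER, secreted modulators of Wnt and bone morphogenetic protein signalling, rose by 3.62 and 3.27 on the log2 scale. COL24A1, a fibrillar collagen chain, rose by 3.57, KLHL2, an adaptor of a ubiquitin ligase, by 3.43, and CADPS2, which acts in vesicle secretion, by 3.38. SAMD3 rose by 3.71 and SNX7, a sorting nexin, by 3.10.

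Among the genes that fell, UNC5D (chromosome 8, 35235457 to 35796550, plus strand), of the netrin receptor family, showed the largest decrease, from 93.4 CPM ± 32.5 in PAD to 11.1 ± 2.77 in PAD-CKD (log2 fold change -2.59 ± 0.33, SE). PTPRQ (chromosome 12, 80402178 to 80680271, plus strand) and PTPN3, both of the protein tyrosine phosphatase family, changed by -1.39 and -1.38, and CFAP61, a cilium-associated protein, by -1.37. SF3A3, a subunit of a splicing factor, changed by -1.32, and ZC2HC1C, IQCH and FAM217A by -1.52, -1.40 and -1.27. The named genes also include the antisense transcripts AQP4-AS1, C9orf147, DPYD-AS1 and PRKG1-AS1, with log2 fold changes of -1.87, -1.72, -1.60 and -1.55, and MSC-AS1 with 3.34. These 5 are uncertain, because the sources do not state whether reads were assigned by strand. For each of these named genes both PAD-CKD libraries lay on the same side of all 3 PAD libraries, because the naming rule required it. Among all genes tested in all myonuclei that was so for 42.7%, where chance gives 20%, and these genes are not independent.

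PAD replicate 1 stood apart from the other PAD libraries. Across the genes tested in all myonuclei, which are not independent replicates, its Pearson correlation was 0.871 and 0.873 with PAD replicates 2 and 3. With PAD-CKD replicates 1 and 2 it was 0.882 and 0.879, so PAD replicate 1 lay no nearer to its own group. PAD replicates 2 and 3 reached 0.967 with each other, as did the 2 PAD-CKD libraries. Between PAD replicates 2 and 3 and the PAD-CKD libraries the correlation was 0.843 to 0.866. The number of genes changed in all myonuclei was 1811 without PAD replicate 1, 4 without PAD replicate 3, and 0 by limma without PAD replicate 2 (1471 at unadjusted p below 0.05), without PAD-CKD replicate 1 (989) and without PAD-CKD replicate 2 (979). With the replicate number as a block it was 0 by limma, with 1195 genes at unadjusted p below 0.05.

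**Figure D2:**
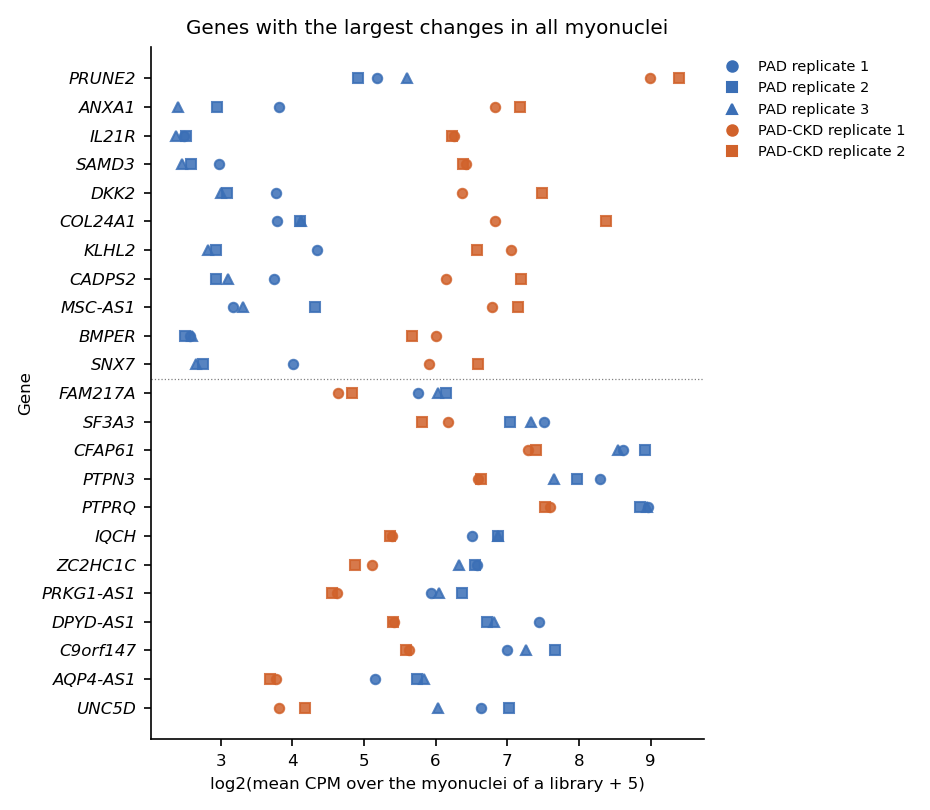
Mean level of the named genes over the myonuclei of each library, as log2 of CPM plus 5, with 1 point per library and the genes ordered by fold change. The PAD-CKD libraries lie to the right of the PAD libraries for the genes above the dotted line, and to the left for the genes below it, as the naming rule required.

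Groups of genes fixed before the data were examined shifted in all myonuclei as well (camera in limma, Benjamini-Hochberg adjusted over 32 lists, with a preset correlation of 0.01 between genes). Of the 64 measured nuclear-encoded genes of oxidative phosphorylation, 63 were lower in PAD-CKD, with a median log2 fold change of -0.63 (adjusted p = 1.1e-10, and adjusted p = 0.785 with an estimated correlation). No single member passed limma over all genes or adjusted over the list alone, and 22 were lower at unadjusted p below 0.05. ATP5F1D, a subunit of the ATP synthase, had a log2 fold change of -1.22 ± 0.22 (SE), and UQCRFS1, of complex III, -1.14 ± 0.27. The list of the TCA cycle and pyruvate dehydrogenase had a median of -0.38 (camera adjusted p = 0.00674, Benjamini-Hochberg; adjusted p = 0.785 with an estimated correlation), with citrate synthase (CS) at -0.99. Fatty acid uptake and oxidation had a median of -0.44 (camera adjusted p = 0.00885, Benjamini-Hochberg; adjusted p = 0.785 with an estimated correlation), with FABP3 at -1.23.

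Slow sarcomere genes had a median log2 fold change of -1.24 in all myonuclei, with 11 of 12 lower (camera adjusted p = 0.00885, Benjamini-Hochberg; adjusted p = 0.785 with an estimated correlation). MYL2, the slow regulatory light chain, was at -2.06 ± 0.64 (SE) and the slow troponin TNNI1 at -1.35 ± 0.41. Within type I myonuclei alone the same 12 genes had a median of 0.05, with 7 higher and 5 lower (camera adjusted p = 0.801, Benjamini-Hochberg). Most of these genes are the markers that named the type I class, so a small change there was in part set by the choice of nuclei. Genes of denervation and the neuromuscular junction had a median of 1.37, with 16 of 20 higher (camera adjusted p = 0.00495, Benjamini-Hochberg; adjusted p = 0.785 with an estimated correlation). Of these, 2 rose past the threshold over all genes and 4 adjusted over the list alone. MYH8, the perinatal myosin heavy chain (chromosome 17, 10390322 to 10421950, minus strand), rose 5.71-fold to 97.0 CPM ± 18.3, and MYH3, the embryonic one (chromosome 17, 10628526 to 10657309, minus strand), rose from 45.6 CPM ± 9.39 to 217 ± 89.2, 4.19-fold. Folds here and below, unless given from UMI counts, come from the fit with 5 CPM added and differ from ratios of the printed CPM. CHRNG, the foetal subunit of the acetylcholine receptor, and NCAM1, which reappears on denervated fibres, had log2 fold changes of 2.29 ± 0.48 and 1.66 ± 0.38 and passed over the list alone. None of the list calls in any class was kept with an estimated correlation or by fry.

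Extracellular matrix genes (9 measured, median log2 fold change 0.88, camera adjusted p = 0.0166, Benjamini-Hochberg) and immediate early genes (18 measured, all higher, median 0.94, camera adjusted p = 0.00885, Benjamini-Hochberg) were higher as lists in all myonuclei, with adjusted p = 0.785 with an estimated correlation for each. SPARC, a matrix glycoprotein, was at 1.38 ± 0.25 (SE). DCN, a marker of fibro-adipogenic progenitors, stood in myonuclei at 23.9 CPM in PAD-CKD and 5.29 in PAD, and in the progenitors, whose share of nuclei was 8.33% and 4.45%, at 1473 and 1866. Immediate early genes included the transcription factor FOSB at 3.23 ± 0.70 (SE). Cytosolic ribosomal protein genes had a median of -0.20, with 52 of 65 lower (camera adjusted p = 0.0121, Benjamini-Hochberg; adjusted p = 0.846 with an estimated correlation). The immediate early genes are also known to respond to tissue handling. No member of these 3 lists passed limma over all genes, while 2, 0 and 0 passed adjusted over the list alone.

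Genes singled out before the data were examined did not pass in all myonuclei. The ubiquitin ligases of muscle atrophy, FBXO32 and TRIM63, had log2 fold changes of 1.15 ± 0.33 and 0.70 ± 0.43 (SE; limma, Benjamini-Hochberg adjusted p = 0.134 and 0.41). PPARGC1A, a coactivator of mitochondrial biogenesis, was at -1.51 ± 0.63, and PDK4, a brake on pyruvate dehydrogenase, at 1.13 ± 0.88 (limma, Benjamini-Hochberg adjusted p = 0.255 and 0.52). The angiogenic factor VEGFA stood at 46.2 CPM ± 5.38 in PAD-CKD and 97.4 ± 24.0 in PAD (limma, Benjamini-Hochberg adjusted p = 0.0945). The myosin heavy chains MYH7, MYH1 and MYH2 were at -1.46 ± 0.64, 0.77 ± 0.62 and 0.63 ± 0.86. AHR, the aryl hydrocarbon receptor, and its target CYP1B1 lay below the minimum level for testing in myonuclei.

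Within single fibre classes no gene passed the threshold in limma with all libraries and the settings chosen here. In type I myonuclei 0 of 8596 genes passed, with 913 at unadjusted p below 0.05 and 0 by limma-voom. In type II myonuclei 0 of 8474 passed, with 773 at unadjusted p below 0.05 and 692 by limma-voom, while limma gave 89 with the replicate block, 38 without PAD replicate 1 and 6 with library-centred clustering. In regenerating or denervated-like myonuclei 0 of 9012 passed, with 829 at unadjusted p below 0.05 and 1349 by limma-voom. The changes in type I and type II myonuclei were compared directly, and 0 of 8614 genes passed, with 354 at unadjusted p below 0.05 and 4 by limma-voom. PRUNE2 in regenerating or denervated-like myonuclei stood at 962 CPM ± 1.56 in PAD-CKD and 94.4 ± 18.2 in PAD (limma, Benjamini-Hochberg adjusted p = 0.0567). The nuclei of this class come from other clusters in each group, 2 of them to 94.1% and 95.7% from PAD replicate 1 and 2 to 98.1% and 87.9% from PAD-CKD, the last led by PRUNE2, so a change within a class is not separated from a change of cluster. ACTN3, a protein of fast fibres, stood at 40.3 CPM ± 3.50 and 8.82 ± 6.01 in type I myonuclei (limma, Benjamini-Hochberg adjusted p = 0.335). MYH7 was at -0.07 ± 0.28 on the log2 scale in type I and at -0.94 ± 0.59 in type II myonuclei. MYH1 was at 1.23 ± 0.42 and 0.99 ± 0.35, and MYH2 at 0.93 ± 0.62 and 0.37 ± 0.51. These myosins are among the markers that named the fibre classes, so their changes within a class are in part set by the naming.

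Fast sarcomere genes in type I myonuclei had a median log2 fold change of 0.61 (camera adjusted p = 0.0218, Benjamini-Hochberg; adjusted p = 0.733 with an estimated correlation), and slow sarcomere genes in type II myonuclei a median of -0.77 (camera adjusted p = 0.0004, Benjamini-Hochberg; adjusted p = 0.817 with an estimated correlation). Transcripts carried over between fibre types were not tested apart, and MYH1 made up 362 of 13506600 UMIs in type I and 69386 of 28454186 in type II myonuclei of PAD-CKD. Oxidative phosphorylation genes had medians of -0.36 in type I, -0.75 in type II and -0.60 in regenerating or denervated-like myonuclei (camera adjusted p = 1.46e-05, 1.07e-17 and 7.62e-10, Benjamini-Hochberg; adjusted p = 0.733, 0.817 and 0.676 with an estimated correlation). Mitochondrially encoded transcripts had medians of -2.52, -3.55 and -2.49 in these 3 classes (camera adjusted p = 0.00306, 1.3e-12 and 0.0355, Benjamini-Hochberg; adjusted p = 0.733, 0.817 and 0.809 with an estimated correlation). In type II myonuclei MT-CO3, a subunit of cytochrome oxidase, stood at 29.5 CPM ± 12.6 in PAD-CKD and 759 ± 390 in PAD, and MT-CYB at 14.7 ± 0.354 and 383 ± 196 (limma, Benjamini-Hochberg adjusted p = 0.25 for each). A type II and a type I cluster led by genes that include MT-CO1, MT-CO2 and MT-CO3 came to 83.4% and 83.6% from PAD replicate 2. A cluster without a name, also led by mitochondrially encoded genes, held 1118 nuclei, 74.5% of them from PAD-CKD replicate 2. It lies in none of these classes, and what leaving it out does to the medians was not tested. MT-CO3 in type II myonuclei stood at 749, 1154 and 375 CPM in PAD replicates 1, 2 and 3. The deposited values hold few mitochondrial UMIs, between 0.0151% and 0.358% of a library, and with each entry listed at 0 counted as 1 UMI the 3 medians were -0.66, -1.16 and -0.93. Type II myonuclei of PAD replicate 1 numbered 55, and regenerating or denervated-like myonuclei of PAD replicate 3 numbered 41.

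In fibro-adipogenic progenitors, 86 of 10461 genes differed, 20 higher and 66 lower in PAD-CKD (limma, Benjamini-Hochberg). PLA2G2A, a secreted phospholipase (chromosome 1, 19975431 to 19980416, minus strand), rose from 19.7 CPM ± 12.9 (SD, n = 3) to 186 ± 59.1 (SD, n = 2), 8.49-fold. COL4A4, a basement membrane collagen chain, rose by 2.29 on the log2 scale, the transcription factor RUNX1 by 1.69, EFNA5, a ligand of Eph receptors, by 1.66, and FGF7, a growth factor for epithelial cells, by 1.66. PCSK5, a proprotein convertase, rose by 1.61, COL24A1 by 1.59, EYA4, a transcriptional coactivator, by 1.41, and ABCC9, a regulatory subunit of ATP-sensitive potassium channels, by 1.37. AKAP6, PLCXD3 and PHLDB2 rose by 2.01, 1.81 and 1.34. HIF3A, of the hypoxia-inducible factor family (chromosome 19, 46297046 to 46343433, plus strand), fell from 206 CPM ± 57.4 to 47.8 ± 7.24, 3.88-fold. SLC5A9, a sugar transporter, changed by -2.13, BRINP3 by -2.01, the lipase gene LIPI by -1.81, ANGPTL1, of the angiopoietin-like family, by -1.65, and ENKUR by -1.59. The 6 other named genes that were lower, DIAPH2-AS1, MAP3K20-AS1, ALG13-AS1, KCNMB2-AS1, ZNF385D-AS2 and ZBTB20-AS2, are non-coding transcripts with log2 fold changes from -2.13 to -1.53, uncertain for the reason given above.

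Among the lists tested in fibro-adipogenic progenitors, ribosomal protein genes were lower (64 of 65, median -0.62, camera adjusted p = 4.63e-13, Benjamini-Hochberg; adjusted p = 0.686 with an estimated correlation; 0 past limma over all genes and 8 adjusted over the list alone). Inflammation and NF-kB target genes were higher in 17 of 17 (median 0.54, camera adjusted p = 6.65e-05, Benjamini-Hochberg; adjusted p = 0.686 with an estimated correlation), with 0 members past limma over all genes and 1 adjusted over the list alone. That member, the cytokine IL6, was counted with 2 UMIs in PAD and 410 in PAD-CKD, a ratio of 153 (95% counting interval 42.1 to 1267). Interferon response genes were higher in 14 of 18 (median 0.51, camera adjusted p = 0.00217, Benjamini-Hochberg; adjusted p = 0.686 with an estimated correlation), 0 of them past limma over all genes and 5 over the list alone, among them NLRC5, a regulator of class I antigen presentation, at 1.43. Levels of common sarcomere genes, which are expressed by fibres, were in these nuclei 4.07% ± 0.163 of those in myonuclei in PAD and 6.12% ± 2.48 in PAD-CKD (exact permutation p = 0.1). The genes changed in fibro-adipogenic progenitors numbered 393 without PAD replicate 1, 0 by limma without each other library (908 to 1627 at unadjusted p below 0.05) and 0 with the replicate block (1438). They numbered 47 when genes opposite a more abundant gene were left out and 0 by limma on recovered UMI sums (1804 at unadjusted p below 0.05), so this count depends on these choices. The balance of 20 higher and 66 lower does too, with 192 and 201 without PAD replicate 1 and 12 and 4 with no filter. In PAD-CKD, AKAP6, EYA4, COL4A4 and RUNX1 stood at 58.1, 74.1, 57.6 and 588 CPM in these nuclei and at 1099, 1129, 355 and 1553 in myonuclei, and carry-over from fibres was not tested for single genes. PCSK5 is among the leading genes of a cluster of 416 progenitors, 87.0% of them from PAD-CKD. Another cluster of 214 progenitors came to 94.4% from PAD replicate 1. A change within the progenitors is thus not separated from a change of cluster.

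In satellite cells, 267 of 10936 genes differed, 119 higher and 148 lower in PAD-CKD (limma, Benjamini-Hochberg). LRP1B, of the LDL receptor family (chromosome 2, 140231423 to 142131701, minus strand), rose from 40.4 CPM ± 9.67 (SD, n = 3) to 406 ± 64.0 (SD, n = 2), 9.36-fold (limma, Benjamini-Hochberg adjusted p = 0.000332). OSBPL10, an oxysterol-binding protein, rose by 3.07 on the log2 scale, the matrix proteoglycan VCAN by 2.99, the collagen chain COL19A1 by 2.79, HDAC9, a class IIa histone deacetylase, by 2.53, and the transcription factor SIM1 by 2.49. PDE1C, a phosphodiesterase, rose by 2.39 and RBM20, a splicing regulator of muscle, by 2.27. PRR16, PTCHD4, REEP1 and SAMD5 rose by 2.68, 2.48, 2.38 and 2.36. DLK1, a Notch-related protein and marker of these cells (chromosome 14, 100725705 to 100738224, plus strand), fell from 155 CPM ± 30.1 to 30.6 ± 14.6, 4.53-fold. MT1X, a metallothionein, changed by -1.88, the lipid carrier APOE by -1.81, ANGPTL1 by -1.84, the transcription factor SIM2 by -1.81, OPRM1, an opioid receptor, by -1.74, the ceramide synthase CERS3 by -2.09, and CHCHD10, a mitochondrial protein, by -1.62. P4HA2-AS1, LURAP1L-AS1 and TTC21B-AS1 changed by -1.64, -1.64 and -1.60 and are uncertain as antisense transcripts.

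Ribosomal protein genes were lower in satellite cells in 65 of 65 members (median -0.73, camera adjusted p = 2.77e-23, Benjamini-Hochberg; adjusted p = 0.585 with an estimated correlation). Of these, 5 fell past the threshold over all genes, among them RPS18 at -1.59, and 36 adjusted over the list alone. Oxidative phosphorylation genes had a median of -0.62, with 61 of 66 lower (camera adjusted p = 3.39e-10, Benjamini-Hochberg; adjusted p = 0.585 with an estimated correlation), 0 past limma over all genes and 8 over the list alone, among them COX5B at -1.69. The matrix list had a median of 0.43 (camera adjusted p = 0.00598, Benjamini-Hochberg; adjusted p = 0.585 with an estimated correlation), and VCAN, COL1A2 and COL5A1 rose by 2.99, 1.07 and 0.79. Common sarcomere genes had a median of 0.39 (camera adjusted p = 0.00404, Benjamini-Hochberg; adjusted p = 0.585 with an estimated correlation), and 4 of them rose, TTN by 0.96, CMYA5 by 1.12, MYPN by 1.81 and TRDN by 0.92. COL19A1 also stood at 933 CPM in myonuclei of PAD-CKD, against 85.3 in satellite cells, HDAC9 at 528 and PRR16 at 438, so carry-over from fibres is not excluded for them. The level of common sarcomere genes was 8.80% ± 1.57 of that in myonuclei in PAD and 12.2% ± 2.32 in PAD-CKD (exact permutation p = 0.3). The genes changed in satellite cells numbered 1003 without PAD replicate 1, 25 without PAD replicate 2, 71 without PAD replicate 3, 3 without PAD-CKD replicate 1 and 0 by limma without PAD-CKD replicate 2 (1042 at unadjusted p below 0.05). The balance turned to 162 higher and 110 lower with no filter, and to 81 and 37 with means of the log values.

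In macrophages and monocytes, 147 of 9596 genes differed, 80 higher and 67 lower in PAD-CKD (limma, Benjamini-Hochberg). NR4A2, an early response nuclear receptor (chromosome 2, 156324432 to 156342348, minus strand), rose from 19.3 CPM ± 16.9 (SD, n = 3) to 411 ± 287 (SD, n = 2), 18.2-fold. The early response factor EGR3 was counted with 2 UMIs in PAD and 272 in PAD-CKD, a ratio of 71.6 (95% counting interval 19.6 to 594), CSRNP1 with 1 and 170 UMIs, a ratio of 89.5 (15.9 to 3556), and CXCL8, the chemokine interleukin 8, with 3 and 223 UMIs, a ratio of 39.1 (13.2 to 191). THBS1, the matrix protein thrombospondin 1, had no UMI in PAD macrophages and was at least 19.0-fold higher in PAD-CKD, taking 3 UMIs over the group as the floor. EPAS1, the hypoxia-inducible factor 2 alpha, rose by 3.36 on the log2 scale. RNASE1, a secreted ribonuclease (chromosome 14, 20801228 to 20803278, minus strand), fell from 234 CPM ± 116 to 35.6 ± 5.93, 5.30-fold in the fit, and DAAM2, a formin of the Wnt pathway, SEMA6A, a semaphorin, and C12orf40 changed by -2.23, -2.15 and -2.43. The other 8 named genes that were lower, among them SCN1A-AS1 at -2.40 and MEF2C-AS2 at -2.16, are antisense or other non-coding transcripts and uncertain.

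As lists in macrophages, immediate early genes were higher in 22 of 22 (median 2.37, camera adjusted p = 3.01e-19, Benjamini-Hochberg; adjusted p = 0.369 with an estimated correlation), with 4 risen over all genes, NR4A2, EGR3, GADD45B at 3.26 and ATF3 at 2.54, and 14 over the list alone. Inflammation and NF-kB targets were higher in 23 of 23 (median 1.54, camera adjusted p = 1.49e-16, Benjamini-Hochberg; adjusted p = 0.323 with an estimated correlation), with 3 risen over all genes, CXCL8, CXCL3 at 2.42 and TNFAIP2 at 1.42, and 17 over the list alone. Class II antigen presentation and complement genes had a median of 0.28 (camera adjusted p = 0.0079, Benjamini-Hochberg; adjusted p = 0.323 with an estimated correlation), and HLA-DQB1 and HLA-DRB1 rose by 1.90 and 1.31. The other named genes that were higher, COL19A1, PTGFR, TP63, GHR, ZFPM2 and ERBB4, were also found in myonuclei of PAD-CKD, at 933, 617, 2576, 1086, 1251 and 1330 CPM. In macrophages COL19A1 and PTGFR had no UMI in PAD and were at least 14.0-fold and 13.7-fold higher in PAD-CKD, and TP63, GHR, ZFPM2 and ERBB4 rose by 3.43, 3.42, 3.38 and 3.37. Common sarcomere genes were higher in 20 of 21 (median 1.31, camera adjusted p = 1.14e-09, Benjamini-Hochberg; adjusted p = 0.323 with an estimated correlation), and their level was 6.13% ± 1.56 of that in myonuclei in PAD, and 11.5% and 11.9% in the PAD-CKD libraries (exact permutation p = 0.1). With all genes at least 10 times as abundant in myonuclei left out, the genes changed in macrophages and monocytes numbered 86, 34 higher and 52 lower, so the balance turned. It was 49 and 124 by limma-voom and 97 and 31 with no filter, while 29 genes passed on recovered UMI sums and 8 with thinned nuclei. They numbered 402 without PAD replicate 1, 68 without PAD replicate 2, 85 without PAD replicate 3, 118 without PAD-CKD replicate 2 and 0 by limma without PAD-CKD replicate 1 (462 at unadjusted p below 0.05).

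In endothelial cells 0 of 8534 genes passed in limma, with 569 at unadjusted p below 0.05 and 27 by limma-voom, and PAD replicate 3 held 32 of these nuclei. The cytoskeletal regulator NAV3 stood at 822 CPM ± 61.1 (SD, n = 2) in PAD-CKD and 71.8 ± 49.3 (SD, n = 3) in PAD, TGFBR3, a co-receptor of TGF-beta, at 379 ± 24.2 and 103 ± 38.5, and FMO2, a monooxygenase, at 51.9 ± 1.93 and 333 ± 140 (limma, Benjamini-Hochberg adjusted p = 0.599 for each). RUNX1 was counted with 3 UMIs in PAD and 193 in PAD-CKD, a ratio of 13.1 (95% counting interval 4.41 to 64.0). It stood at 107 CPM in endothelial cells of PAD-CKD and at 1553 in myonuclei, and common sarcomere genes were in endothelial nuclei at 10.8% ± 5.31 of their level in myonuclei in PAD and 6.63% ± 1.78 in PAD-CKD (exact permutation p = 0.5). The median over all genes tested here was 0.18. Against it, immediate early genes had a median of 1.86 and inflammation and NF-kB targets one of 1.49 (camera adjusted p = 1.37e-07 and 2.86e-07, Benjamini-Hochberg; adjusted p = 0.498 with an estimated correlation for each). Interferon response genes had a median of -0.42 (camera adjusted p = 0.00445, Benjamini-Hochberg; adjusted p = 0.619 with an estimated correlation), and angiogenesis genes one of -0.13 (camera adjusted p = 0.0342, Benjamini-Hochberg; adjusted p = 0.498 with an estimated correlation). No member of these 4 lists passed limma over all genes.

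**Figure D3:**
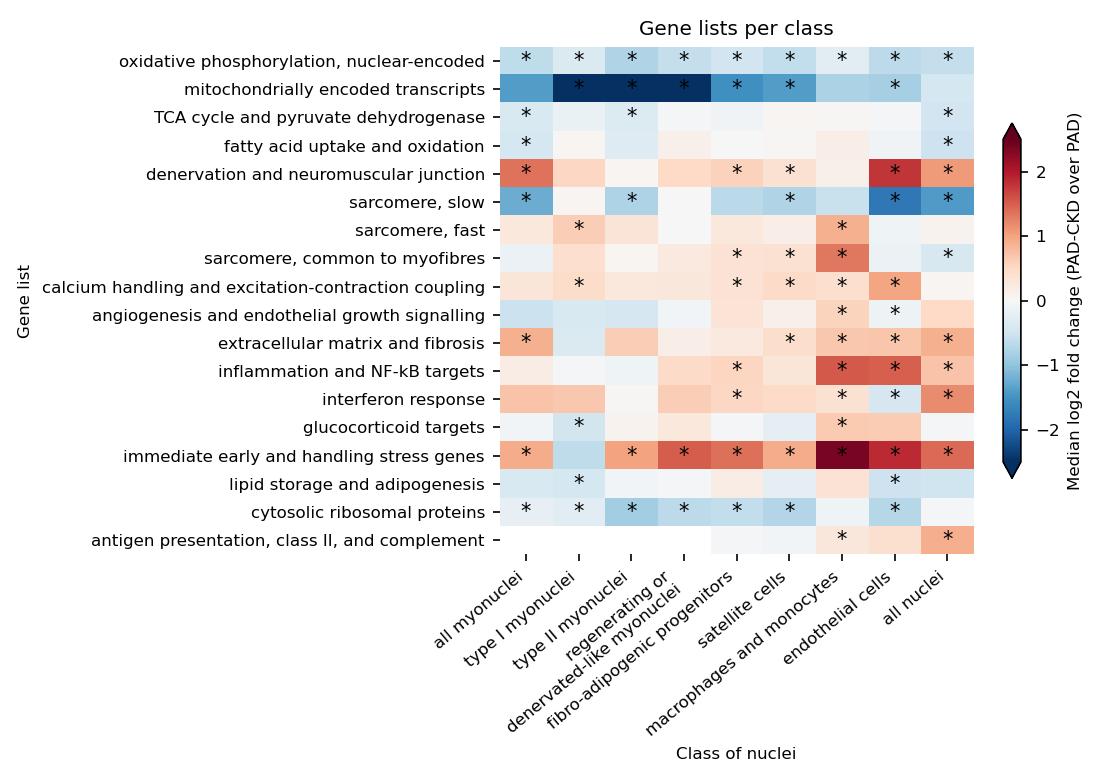
Median log2 fold change (PAD-CKD over PAD) of 18 of the 34 fixed gene lists in each class of nuclei, with red for higher and blue for lower in PAD-CKD and a star where camera passed 0.05 after Benjamini-Hochberg adjustment within the class. Only lists with a star in more than a single class were drawn, so stars are denser here than over all fixed lists. The top line, oxidative phosphorylation, is below 0 in all 9 groups of nuclei, between -0.75 and -0.28, and no star was kept with an estimated correlation or by fry.

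With all nuclei of a library pooled, which also carries the differences in class shares, 593 of 9833 genes differed, 299 higher and 294 lower in PAD-CKD (limma, Benjamini-Hochberg). ADGRV1, an adhesion receptor, SLC2A3, a glucose transporter, SRGN, a proteoglycan of blood cells, and the metalloprotease ADAM12 rose by 3.44, 2.94, 2.81 and 2.52 on the log2 scale, and ANXA1, PRUNE2 and IL21R by 3.39, 3.30 and 3.19. EFNA5 rose from 21.6 CPM ± 3.05 (SD, n = 3) to 156 ± 2.94 (SD, n = 2). COL24A1, DKK2, CERKL and RALYL rose by 3.09, 3.08, 2.98 and 2.78. PLIN5, a lipid droplet protein, fell from 125 CPM ± 37.7 (SD, n = 3) to 34.2 ± 11.8 (SD, n = 2), and GOT1, an aspartate aminotransferase, from 77.6 ± 22.6 to 22.3 ± 1.81. UNC5D, PTPRQ, CFAP61, LRRTM3, ZC2HC1C and PTPN3 changed by -2.74, -1.70, -1.68, -1.66, -1.71 and -1.65. The antisense transcripts C9orf147, AQP4-AS1, PRKG1-AS1 and TTN-AS1 changed by -1.94, -1.87, -1.73 and -1.64 and are uncertain. Matrix genes were higher in 29 of 29 (median 0.89, camera adjusted p = 5.44e-07, Benjamini-Hochberg; adjusted p = 0.625 with an estimated correlation), with COL12A1, VCAN, FBN1, TIMP3 and COL1A2 risen over all genes and 14 over the list alone. The list for targets of the aryl hydrocarbon receptor, a sensor of tryptophan metabolites and other ligands, also holds the receptor gene AHR itself. Its members were higher in 5 of 5 measured (median 1.11, camera adjusted p = 0.00696, Benjamini-Hochberg, and adjusted p = 0.625 with an estimated correlation). AHR and TIPARP passed over all genes, risen by 2.16 and 1.11, and 3 members passed over the list alone. Interferon response genes had a median of 1.17 and class II antigen presentation and complement genes one of 0.92 (camera adjusted p = 0.0015 and 0.00146, Benjamini-Hochberg; adjusted p = 0.625 with an estimated correlation for each), with 1 and 3 members risen over all genes and 3 and 7 over the list alone. The genes changed in all nuclei numbered 1995 without PAD replicate 1, 0 by limma without each other library (1338 to 2361 at unadjusted p below 0.05) and 0 with the replicate block (1924). With no filter on low values only 6 passed, 4 higher and 2 lower.

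Genes that overlap another gene on the opposite DNA strand formed a group of their own among the decreases. In all myonuclei 196 tested genes lay opposite a gene at least 10 times as abundant, and their median log2 fold change was -0.53, against 0.00 for genes with no such neighbour on either strand. Of the genes called, 7 of 89 lower and 1 of 132 higher ones were of this kind (Fisher's exact test, p = 0.0079), and in all nuclei 33 of 294 and 1 of 299 (Fisher's exact test, p = 6.57e-10). Their median level was 7.02%, 6.16% and 5.75% of that of the gene on the other strand in PAD replicates 1, 2 and 3, and 3.70% and 3.88% in PAD-CKD replicates 1 and 2. The gene pairs were taken from the annotation, in which 92.8% of the genes in the files had a match.

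**Figure D4:**
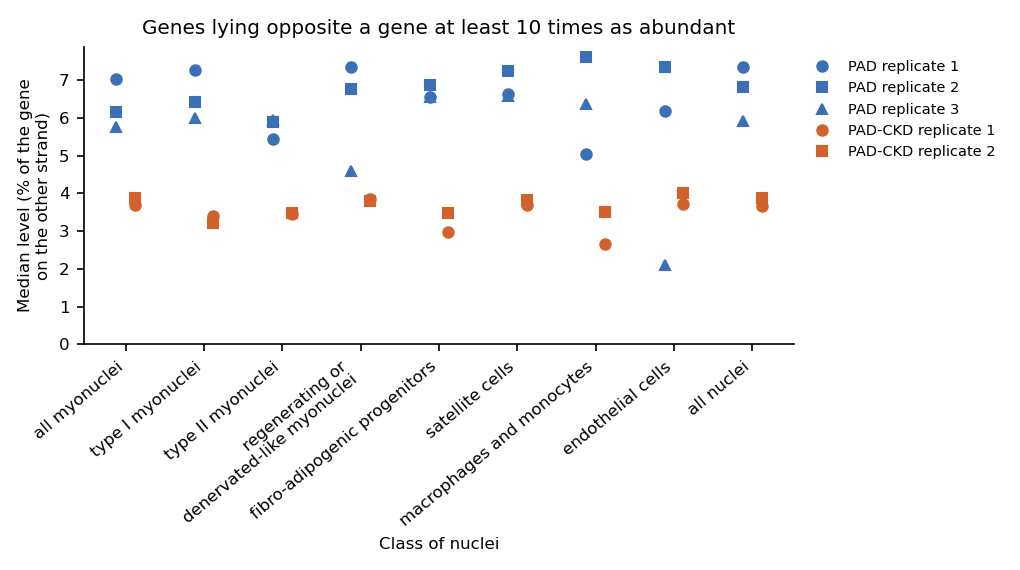
Median level of genes lying opposite a gene at least 10 times as abundant, in percent of that gene, with 1 point per library in each class of nuclei. In all myonuclei the PAD libraries lie between 5.75% and 7.02% and the PAD-CKD libraries at 3.70% and 3.88%, while endothelial nuclei of PAD replicate 3 lie below both PAD-CKD libraries.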

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

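The tests of other splits, of a structure of the libraries, of single clusters, of reads from the opposite strand and of cytoplasmic RNA were chosen only after the result was seen.

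A signal outside the main measurement differed between the groups. The files list entries with the value 0, which sparse files do not need, and these made up 4.89% ± 0.108 (SD, n = 2) of the listed entries in PAD-CKD and 2.97% ± 0.490 (SD, n = 3) in PAD (exact two-sided permutation p = 0.1, the smallest possible). Among ribosomal protein genes they made up 24.0% in PAD-CKD and 52.2% in PAD, and among mitochondrially encoded genes 82.0% and 75.4%. The processing that left these entries is not stated.

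The first pattern is the 221 genes changed in all myonuclei. A change in the mix of myonuclear clusters cannot be told apart from a group difference. The bound set before, met by a median change of 0.81 in the direction of the call and 95.5% of signs kept in type I myonuclei, was wrong, since only 670 of the 2685 type I myonuclei of PAD-CKD lay in clusters with 20 nuclei in every library. Within the 3 such clusters the medians were 0.68, 0.61 and 0.31, with 83.3%, 89.1% and 61.4% of signs kept. The first and last of these clusters held 30 and 20 nuclei of PAD replicate 1 and 22 and 24 of PAD-CKD replicate 2. The 221 genes were called from means that include these nuclei, so some keeping of signs was set in advance. With nuclei thinned to 1000 UMIs the median change was 1.53, against 1.52 before. This cannot decide on a cause in UMIs per nucleus, since random thinning keeps the mean CPM of a gene the same on average. Of the 10 splits of the 5 libraries, 2 gave as many genes, the real split with 221 and the highest other with 263, and 10 splits are too few for a share under 0.05. The split with 263 genes sets PAD replicates 2 and 3 against the other libraries, which points to a structure of the libraries other than the groups in all myonuclei, while a difference due to kidney disease stays open and untested. Elsewhere the real and the highest other split gave 593 and 0 genes by limma in all nuclei, 147 and 1 in macrophages, 86 and 5 in fibro-adipogenic progenitors, 267 and 79 in satellite cells, 0 and 4 in endothelial cells, 0 and 1 in type II myonuclei, and 0 and 0 in the other 2 fibre classes.

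The second pattern is the lower level in PAD-CKD of genes that lie opposite a more abundant gene. A lower level of the gene on the other strand is argued against, since the partner genes had a median log2 fold change of 0.15 in all myonuclei and the 196 genes opposite them one of -0.53. A share of reads from the opposite strand that was higher in all PAD libraries may contribute. Medians were -0.68 in fibro-adipogenic progenitors, -0.54 in satellite cells and -0.71 in macrophages, but -0.083 in endothelial cells, where 1 PAD library held 32 nuclei, so this explanation and a group difference cannot be told apart.

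The third pattern is the lower level of oxidative phosphorylation genes and mitochondrial transcripts in PAD-CKD. For the nuclear-encoded list in all myonuclei, the tables argue against the entries at 0 as the cause, since the median was -0.77 with each counted as 1 UMI and -0.63 before. For the mitochondrially encoded list in type II myonuclei the median was -1.16 in place of -3.55, 32.8% of its size, which met the bound set before for the entries at 0. This cannot decide on them, since counting each as 1 UMI raises every library and so shrinks a fold change of any cause. Mitochondrial UMIs rose from 0.0151% to 0.141% in PAD replicate 1 and from 0.0810% to 0.196% in PAD-CKD replicate 2. The share of mitochondrial entries at 0 gave an exact permutation p of 0.9 between the groups. Mitochondrial UMIs over whole libraries overlapped between the groups, since PAD replicate 1 held 0.0151%, below both PAD-CKD libraries, and PAD replicate 2 the most with 0.358%. The cluster of 1118 nuclei without a name, led by mitochondrially encoded genes, came to 83.1% from PAD-CKD and lay outside the fibre classes. For these transcripts the naming of clusters and a change within a class therefore cannot be told apart. Less cytoplasmic RNA carried over with the nuclei of PAD-CKD is not settled, since ribosomal protein medians lay below -0.1 in 8 of 9 groups of nuclei, with the highest at -0.026 in all nuclei. A difference due to kidney disease stays open and untested.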

How the results depend on the processing

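The settings with another pseudocount, no scaling, recovered UMI sums, voom, entries at 0 counted as 1 UMI, genes on the opposite strand left out, thinned nuclei, means of the log values and naming by the highest fibre state, which leaves no other myonuclei, or with a marker among the 10 leading genes were chosen after the data were seen. The planned DESeq2 and edgeR tests were not run, nor the planned edgeR tests of nuclei counts. This was a choice to match the tests to the deposited log values, and counts could have been tested, since UMIs were recovered and nuclei were counted. In endothelial cells 1000 UMIs per nucleus and thinning gave no value, as 1 library held under 20 nuclei. The cause of the changes below was not tested, except that leaving out a library leaves fewer samples, and with 1 PAD-CKD library left it is assumed to vary like the PAD libraries.

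Without 1 library in turn, the genes changed in all myonuclei numbered 0 to 1811 (221 with all libraries), all nuclei 0 to 1995 (593), fibro-adipogenic progenitors 0 to 393 (86), macrophages and monocytes 0 to 402 (147), satellite cells 0 to 1003 (267), type II myonuclei 0 to 38 (0), and genes whose change differs between type I and type II myonuclei 0 to 1 (0), by limma. In each of these 7 results the highest count came without PAD replicate 1. All 221 genes changed in all myonuclei were among the 1811. The gene lists changed per class numbered 78 to 100 (83).

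With the replicate block the counts were 0 in all myonuclei (1195 at unadjusted p below 0.05), 0 in all nuclei (1924), 0 in fibro-adipogenic progenitors (1438), 2 in endothelial cells and 89 in type II myonuclei. With no filter on low values they were 6 in all nuclei, 16 in fibro-adipogenic progenitors and 257 in all myonuclei, of which 94 were among the 221. With doublets kept they were 2 in endothelial cells, 135 in fibro-adipogenic progenitors and 1 in regenerating or denervated-like myonuclei. With at least 1000 UMIs per nucleus 45 passed in fibro-adipogenic progenitors. Library-centred clustering gave 6 in type II myonuclei and 1 for the difference between type I and type II. With background genes left out 86 passed in macrophages.

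Recovered UMI sums gave 129 genes in all myonuclei, 0 in fibro-adipogenic progenitors (1804 at unadjusted p below 0.05) and 29 in macrophages. Limma-voom gave 1 in all myonuclei, 358 in all nuclei, 27 in endothelial cells, 0 in fibro-adipogenic progenitors (1970), 1349 in regenerating or denervated-like myonuclei, 692 in type II myonuclei and 4 for the difference between type I and type II. Means of the log values gave 81 in all myonuclei, 363 in all nuclei, 23 in endothelial cells, 16 in fibro-adipogenic progenitors, 72 in macrophages, 1 in regenerating or denervated-like myonuclei and 118 in satellite cells. Thinned nuclei gave 382 in all nuclei, 0 in fibro-adipogenic progenitors (1440), 8 in macrophages and 146 in satellite cells. A pseudocount of 1 gave 50 in fibro-adipogenic progenitors and 88 in macrophages, and one of 20 gave 1 in endothelial cells, 36 in fibro-adipogenic progenitors, 1 in regenerating or denervated-like myonuclei and 3 for the difference between type I and type II. The balance of directions changed as well. In all myonuclei 132 genes were higher and 89 lower, but 223 and 34 with no filter and 66 and 15 with means of the log values. In fibro-adipogenic progenitors 20 were higher and 66 lower, but 192 and 201 without PAD replicate 1, 12 and 4 with no filter and 11 and 5 with means of the log values. In macrophages 80 were higher and 67 lower, but 34 and 52 without background genes, 49 and 124 by limma-voom and 97 and 31 with no filter. In satellite cells 119 were higher and 148 lower, but 162 and 110 with no filter and 81 and 37 with means of the log values. No scaling gave 1 in endothelial cells, entries at 0 counted as 1 UMI gave 148 in fibro-adipogenic progenitors, and leaving out genes opposite a more abundant gene gave 47 there. The gene lists changed per class numbered 0 with camera at an estimated correlation and 1 with fry. That list was not among the 83 called in the main test, of which fry kept none.

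The difference in a class share of nuclei reversed in 8 cases, type II myonuclei named by the highest fibre state (-10.9 percentage points), regenerating or denervated-like myonuclei with a marker among the 10 leading genes (-2.16), unnamed nuclei with library-centred clustering (-4.10), T and NK cells without PAD-CKD replicate 2 (-0.429), type II myonuclei without PAD replicate 1 (-11.6) or PAD-CKD replicate 1 (-10.8), and other myonuclei without PAD replicate 2 (-1.73) or PAD replicate 3 (-1.67). Without 1 library the differences ranged from -0.429 to 2.12 for T and NK cells, -21.8 to -10.5 for all myonuclei, 1.45 to 3.82 for endothelial cells, 3.42 to 4.25 for fibro-adipogenic progenitors, 1.74 to 3.99 for macrophages and monocytes, 0.183 to 0.203 for mast cells, 0.361 to 2.48 for mural cells, -1.73 to 16.6 for other myonuclei, 3.33 to 18.2 for regenerating or denervated-like myonuclei, 0.99 to 2.26 for satellite cells, -58.9 to -19.6 for type I among type I and type II myonuclei, -37.6 to -24.5 for type I myonuclei, -11.6 to 12.5 for type II myonuclei, 0.48 to 4.9 for unnamed (percentage points). Named genes kept direction and side of the threshold in 978 of the fits that left out a library and in 4117 of the other fits, passed newly in 40 and 69, and no longer passed in 597 and 671. The lists did so in 347 and 153, and no longer passed in 68 and 179. No named gene and no list reversed. Simulated 2-fold changes were recovered to 1.56% in endothelial cells, 64.2% in all myonuclei, 61.2% in type I myonuclei, where 0 genes passed by limma (913 at unadjusted p below 0.05), and 32.8% and 34.3% in satellite cells and macrophages. The simulation gave every class the same spread and no structure of the libraries, so these rates do not give the power in the real data.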

Other observations

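Several clusters came almost entirely from 1 group or library. A cluster of 4937 other myonuclei, led by PPP1R27, RRAD, FOXO1 and ANKRD1, came to 97.7% from PAD replicate 1, and a cluster of 3204 type I myonuclei to 99.4%. A regenerating or denervated-like cluster of 2792 nuclei, led by genes that include FBXO32, PFKFB3, PDK4 and TRIM63, came to 98.1% from PAD-CKD, and one of 2116 nuclei with PRUNE2, NCAM1, MYH3 and RUNX1 to 87.9%. A cluster of 2702 other myonuclei with PTGFR, COL19A1, ADGRV1 and COL24A1 came to 99.2% from PAD-CKD and to 90.6% from PAD-CKD replicate 2. A cluster of 416 fibro-adipogenic progenitors with VCAN, ADAM12, PCSK5 and FOSB came to 87.0% from PAD-CKD. The cluster without a name held 1118 nuclei with a median of 911.5 UMIs, 74.5% of them from PAD-CKD replicate 2, and was led by mitochondrially encoded genes.

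Mitochondrially encoded genes held 0.0151%, 0.358% and 0.0953% of the UMIs in PAD replicates 1, 2 and 3, and 0.0291% and 0.0810% in PAD-CKD replicates 1 and 2. Over the 10 pairs of libraries, between 0.229% and 0.499% of the barcodes of the smaller library were shared. Libraries with the same replicate number had a Pearson correlation of -0.129 and -0.0166 across genes in all myonuclei after the group means were removed, and between -0.156 and 0.196 over the 9 groups of nuclei. With 2 PAD-CKD libraries these values mirror each other, so they do not settle whether the numbers pair the libraries. The barcodes of PAD replicates 2 and 3 carry the numbers 3 and 4 in their prefix.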
